A study of Mus musculus with 37 samples.

How the data were processed

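RNA from 37 samples of 9 components of the developing mouse kidney was measured on 1 Affymetrix array each. Per the labels, tissue at embryonic days E11.5, E12.5 and E15.5 was collected from 5 kidneys a sample as about 50 sections, the RNA was amplified in 2 rounds, labelled with biotin and hybridized. The authors computed the deposited values as signal intensity with the Affymetrix GCOS software, whose version is not given, and scaled each array. The deposited table was checked: the 2% trimmed mean of every array was 1500, so values are on a linear scale after global scaling and were not normalized further by the authors. All 37 columns were matched to samples by identifier. The table has 45101 probe sets, of which 64 are controls. A single gene is given for 34945 of them (77.6%), several genes for 932 and none for 9160; probe sets with several genes or none were normalized with the others and then not used. Of the symbols, 34741 matched the mouse reference list.

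Signals were increased by an offset of 34.62, the 20th percentile of all values, and transformed to log2. Arrays were quantile normalized, because between arrays the log2 lower quartiles differed by up to 1.64, the medians by 1.40 and the upper quartiles by 0.825. Probe sets above the pooled median (7.89 on the log2 scale) in at least 2 arrays were kept, which left 35806 of all probe sets, 29068 of them with a single gene. For each gene the probe set with the highest mean was used, giving 15709 genes, of which 7499 had several probe sets. The offset makes fold changes of weakly expressed genes smaller than they were. Detection calls are not part of the table, so no lower bound on a fold change is given for genes near background.

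A linear model with 1 mean per component was fitted to all arrays with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend (28 residual degrees of freedom, median prior 7.36). There were 13 comparisons. In 7 of them 2 components were compared: ureteric bud with metanephric mesenchyme, renal vesicle with mesenchyme, S-shaped body with renal vesicle, renal corpuscle with S-shaped body, proximal tubule with S-shaped body, ureteric tip with medullary collecting duct, and ureteric tip with ureteric bud. In the other 6, each component of day E15.5 was compared with the mean of the other 5. P-values were adjusted over all genes of a comparison by the method of Benjamini and Hochberg. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05 with a log2 fold change of at least 1 in size. Values are means with the SD, and SE is the standard error of the log2 fold change. For the other 5 components of day E15.5, the mean given is the unweighted mean of their component means. The SD beside it is taken over all their arrays, so it also holds differences between components. For the 7 pairs, genes whose 2 components did not overlap were also counted, with the share that random labels give.

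Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over all 299 tests of 23 lists. They describe the components (nephron progenitor, ureteric epithelium, ureteric tip, collecting duct, renal vesicle, podocyte, endothelial, mesangial and mural, proximal tubule, loop and distal tubule, interstitium), other cells and states (epithelial junction and keratin, erythroid, macrophage, neural and neural crest, cell cycle, immediate early and heat shock) and pathways (Notch, Wnt target, receptor tyrosine kinase target, hypoxia and glycolysis, oxidative phosphorylation and fatty acid oxidation, basement membrane). Of 310 listed symbols, 281 were measured. Members called are counted over all genes and adjusted over the list alone. There were 135 list calls, of which 32 held with an estimated correlation.

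The genes named were drawn from a set fixed by rule before the data were examined. The set held, for the 7 pairs and the interstitium, the 8 largest calls without overlap in each direction, and for the other 5 components the 6 largest rises. From each list it held up to 4 members, the 3 largest calls and the largest in the other direction or not called. Genes without a descriptive symbol were skipped. From that set, genes with known roles are named and the remainder is given as counts. Nphs1, Wnt4, Dll1 and Lhx1 in single arrays, Egr1 in the plot, and Eif2s3y and Kdm5d were chosen after their values were seen.

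The alternatives tried were 2 other offsets, scaling without quantile normalization, no filter and a stricter filter, the probe set with the largest variance, leaving out probe sets with suffix _x_at or _s_at, array weights, fitting only the samples compared, the date code of the titles as a fixed term or random block, the replicate number of the titles as a block, the way of obtaining the tissue named in the titles, and leaving out each replicate in turn. The sample descriptions name laser capture also where titles name dissection or collagenase, and this was not resolved. Of the dates in the titles, 6 are shared by more than 1 component; dates were fitted as blocks, and tip and collecting duct were also compared within their 2 shared dates alone (4 arrays). Since not every array has a partner of the same date, no paired test over all arrays was made. Comparisons with at least 3 samples a component were repeated on other splits of the samples. Simulated data were drawn independently for each gene, from a normal distribution with the same spread in all arrays. They held no correlation between genes, no unequal spread of components, no date or handling differences and no aberrant arrays. Wrong calls and recovery in the real data may therefore differ from the simulated figures. The procedure was tested on these simulated data with 50 changed genes of each size. Among unchanged genes it wrongly called 5 for bud and mesenchyme, 6 for vesicle and mesenchyme and 6 for S-shaped body and vesicle. It also wrongly called 13 for corpuscle and S-shaped body, 3 for proximal tubule and S-shaped body, 8 for tip and collecting duct and 7 for tip and bud. Of changes of log2 2 and 3, it called 62% and 90% for bud and mesenchyme, 86% and 96% for vesicle and mesenchyme, 56% and 82% for S-shaped body and vesicle, 54% and 90% for corpuscle and S-shaped body, 38% and 64% for proximal tubule and S-shaped body, 48% and 80% for tip and collecting duct, and 54% and 86% for tip and bud. Image files of the arrays were not used here.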

Results

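Transcripts were measured in 37 samples of 9 components of the developing mouse kidney, each hybridized to 1 Affymetrix whole-genome array. At embryonic day E11.5 the metanephric mesenchyme, which gives rise to the nephrons and stroma, was sampled 8 times. The ureteric bud, the epithelial outgrowth that becomes the collecting system, was sampled 4 times on that day. The renal vesicle, the first epithelial stage of the nephron, gave 5 samples at embryonic day E12.5. At embryonic day E15.5 there were 4 samples of the S-shaped body, 4 of the renal corpuscle, 2 of the proximal tubule, 3 of the ureteric tip, 3 of the medullary collecting duct and 4 of the medullary interstitium. Per the labels, a sample was a pool of about 50 sections from 5 kidneys of the outbred CD-1 strain, and its RNA was amplified in 2 rounds. The median deposited signal of an array ranged from 127 to 334. For 29 of the 37 arrays, the most highly correlated other array belonged to the same component. Within components, the Pearson correlation between arrays (across genes, which are not independent replicates) was highest in the ureteric bud, at 0.963 to 0.979, and reached down to 0.734 in the renal corpuscle. The number of arrays limits the precision of each comparison. The error terms measure the spread between pooled samples. The animals behind each pool are not given, and components may share animals, so that p-values may be too small.

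**Figure D1:**
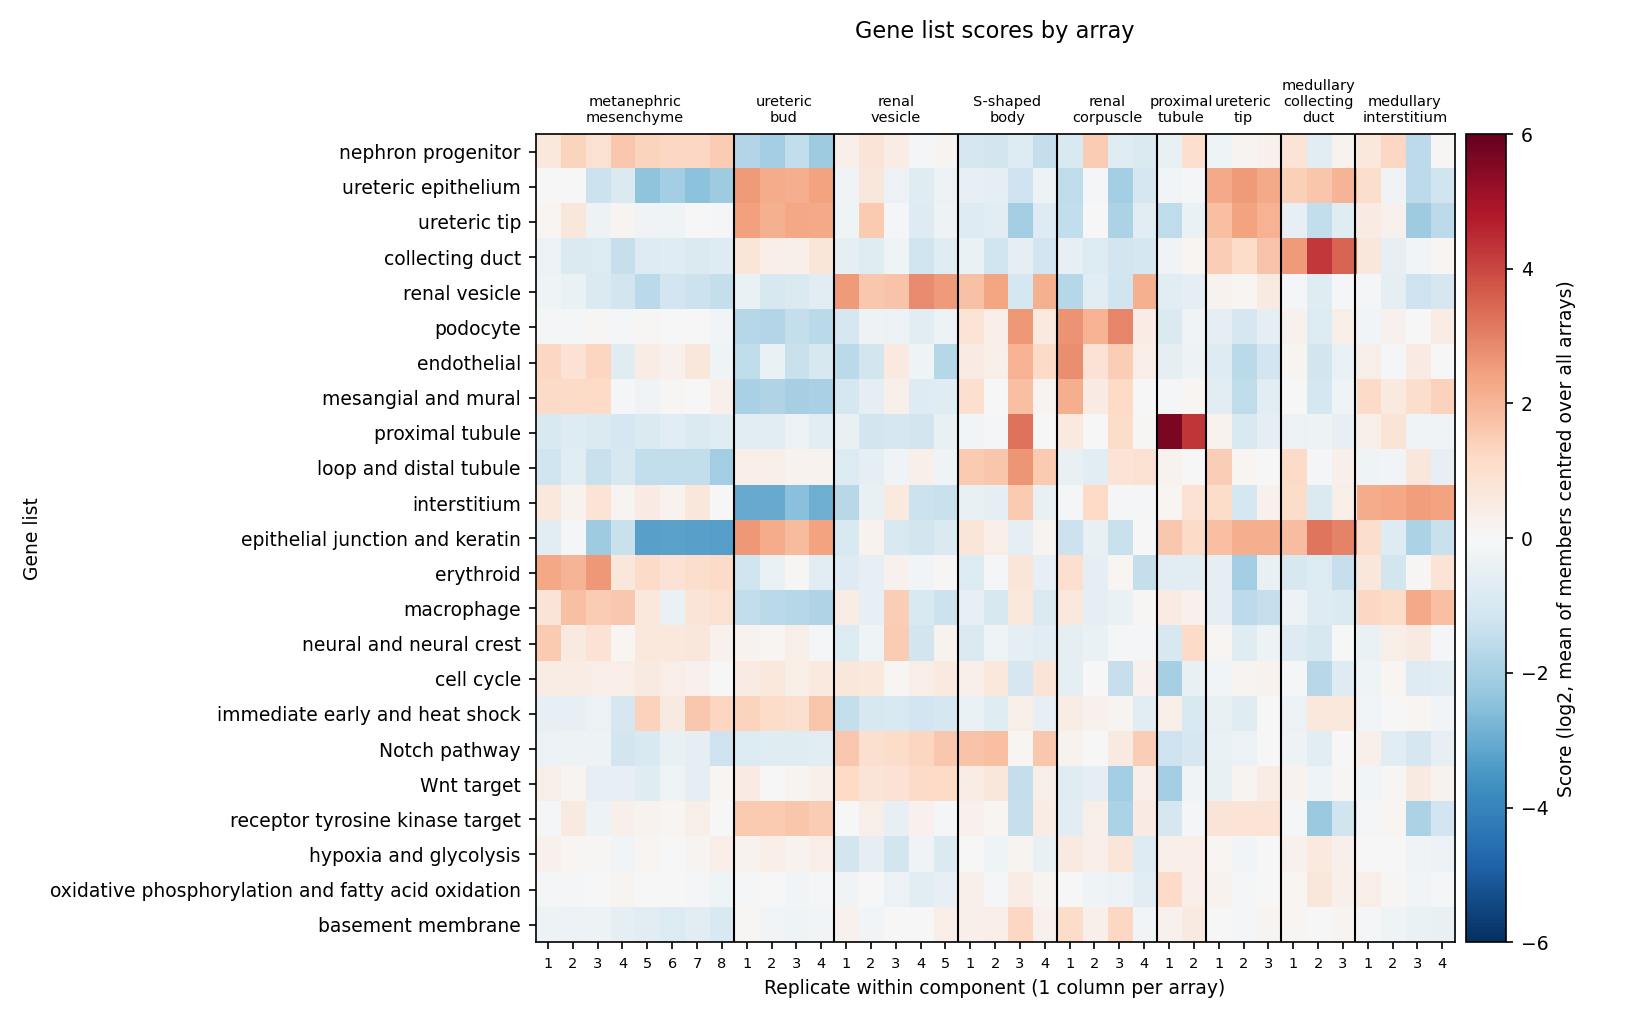
Scores of 23 gene lists (rows) in each of the 37 arrays (columns, grouped by component), as the mean log2 signal of the list's members after each gene was centred over all arrays. The proximal tubule list was highest in the 2 proximal tubule arrays, and the library labelled S-shaped body replicate 3 showed a podocyte score of 2.59 and a proximal tubule score of 3.27.

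The ureteric bud was compared with the metanephric mesenchyme to ask which genes separate the 2 tissues that begin the kidney. Epithelial genes were far higher in the bud. Cldn7, a tight junction claudin (probe set 1448393_at), reached 15.10 ± 0.31 (log2 signal, SD, n = 4) against 9.05 ± 2.46 (SD, n = 8), and rose by 6.05 (SE 0.87, adjusted p = 5.35e-06). The splicing factor gene Esrp1 rose by 6.16, Pkhd1, mutated in recessive polycystic kidney disease, by 5.88, and the cadherins Cdh16 and Cdh1 by 5.66 and 5.10. Ret, the receptor through which the mesenchyme's Gdnf drives branching, rose by 5.33 (SE 1.21, adjusted p = 0.00236), while Gdnf itself fell by 5.27 (SE 1.07, adjusted p = 0.000661). The calcium binding protein gene Calb1 reached 16.60 ± 0.03 in the bud and rose by 5.84. Epithelial genes varied widely in the mesenchyme: the score of the epithelial junction and keratin list was -2.11 to -0.105 in its replicates 1 to 4 and -3.28 to -3.23 in replicates 5 to 8. In the other direction, the stromal and mesenchymal forkhead genes Foxc2 and Foxd1 fell by 6.21 (SE 0.46, adjusted p = 6.65e-12) and 6.16 (SE 0.78, adjusted p = 6.45e-07). The progenitor regulators Eya1, Meox1 and Wt1 fell by 5.48, 5.10 and 4.36, the Wnt agonist Rspo3 by 5.76, the positional homeobox gene Hoxd10 by 5.68 and the atypical cadherin Fat4 by 5.66. All genes named in this comparison so far differed without overlap between the 4 bud and 8 mesenchyme arrays, which the rule for naming the largest changes required. Of 15709 genes, 639 were called higher and 639 lower in the bud by limma. With the title date as a fixed term, undated arrays add nothing. The comparison then rested on 1 bud and 1 mesenchyme array that share a date, with Cldn7 at 7.54 and Foxc2 at -5.00. With the date as a random block, 1287 genes were called. For 2087 genes the 2 components did not overlap, which is 13.3% of genes against 0.404% by chance.

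As sets, the epithelial junction and keratin list rose in the bud, with 15 of 16 members called over all genes and 16 adjusted over the list alone (median log2 fold change 4.55, camera adjusted p = 3.74e-32). The ureteric epithelium list rose likewise, with 12 of 14 members called and 13 adjusted over the list alone (median 4.20, adjusted p = 1.53e-19). The nephron progenitor list fell, with 9 of 13 members called and 11 adjusted over the list alone (median -3.07, adjusted p = 3.24e-17), as did the interstitium list, with 13 of 19 and 15 (median -3.34, adjusted p = 7.63e-25). Its members Col3a1, a fibrillar collagen gene of stroma, and Pdgfra, a growth factor receptor gene, fell by 5.46 and fell by 5.35. Other tissues present in the mesenchyme also separated the samples. The macrophage list fell in 8 of 11 members and in 11 adjusted over the list alone (median -2.18, adjusted p = 2.54e-11), and its member Csf1r, a receptor gene that macrophages need, fell by 4.73. The mesangial and mural list fell in 6 of 9 members, and in 6 adjusted over the list alone (median -2.42, adjusted p = 1.4e-08), with the pericyte proteoglycan gene Cspg4 down by 4.74 on 1 of its 2 probe sets. The erythroid list fell in 5 of 9 members and 6 adjusted over the list alone (adjusted p = 3.58e-06, and adjusted p = 0.0622 with an estimated correlation). Genes of the receptor tyrosine kinase feedback response were higher in the bud: Spry1 rose by 2.65 (SE 0.33, adjusted p = 4.59e-07), and 2 of 7 members of that list were called (2 adjusted over the list alone, adjusted p = 0.000372, and adjusted p = 0.112 with an estimated correlation). Etv5 was 1.53 higher but not called (SE 1.09, adjusted p = 0.598), though it was called with array weights (1.67), with only the samples compared (1.53) and with the title method as a fixed term (1.35). Neural and neural crest genes gave no call as a list in any of the 13 comparisons (8 members, smallest adjusted p = 0.284).

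The renal vesicle was compared with the mesenchyme it forms from, 1 embryonic day earlier. Lhx1, a homeobox gene needed for nephron patterning (probe set 1450428_at), reached 12.99 ± 1.35 (SD, n = 5) against 7.30 ± 1.52 (SD, n = 8) and rose by 5.68 (SE 1.00, adjusted p = 0.000188). The lectin gene Clec18a rose by 5.90 (SE 0.57, adjusted p = 4.31e-08), the chloride channel gene Ano1 by 5.08, Papss2, which makes the sulfate donor, by 4.75, and the chemokine gene Cxcl14 by 4.54. Wnt4, the signal that turns mesenchyme into epithelium, rose by 3.54 (SE 0.69, adjusted p = 0.00059), Cdh1 by 4.12 and the cyclin gene Ccnd1 by 2.43. The Notch ligands Jag1 and Dll1 rose by 3.75 (SE 0.40, adjusted p = 1.35e-07) and 3.30, and the Notch target Hes5 by 2.99. Among falls, Isl1, a homeobox gene of mesenchyme near the nephric duct, fell by 6.89 (SE 0.88, adjusted p = 2.74e-06), Mamdc2 by 6.24, the protocadherin gene Pcdh8 fell by 6.03, the cofactor gene Zfpm2 by 4.95 and Sall4 by 4.36. Six2, which keeps nephron progenitors undifferentiated, fell by 3.30 (SE 0.61, adjusted p = 0.000327), and Meox1 by 3.48. Against only the 3 mesenchyme arrays titled LCM (laser capture microdissection), Six2 was at -1.86 and Meox1 at -3.20, neither called. Gdnf was not called, at -2.13 (SE 0.99, adjusted p = 0.152), though it was called with only the samples compared (SE 0.27, adjusted p = 0.000104).

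By limma, 608 genes were called higher and 1246 lower in the vesicle. The ranges did not overlap for 1019 genes (6.49%, against 0.155% by chance). The renal vesicle list rose in 14 of 15 members, and in 14 adjusted over the list alone (median 2.99, adjusted p = 1.8e-18). The Notch pathway list rose in 8 of 10 members, and in 8 adjusted over the list alone (median 1.79, adjusted p = 4.5e-10). The basement membrane list had 4 rises and 1 fall among 14 members, the same adjusted over the list alone (adjusted p = 9.87e-05, and adjusted p = 0.0659 with an estimated correlation), and its laminin chain gene Lamb1 rose by 1.65 (SE 0.19, adjusted p = 3.17e-07). Lists of other cells fell: interstitium in 9 of 19 members with 1 rise (10 and 1 adjusted over the list alone, adjusted p = 0.000324, and adjusted p = 0.337 with an estimated correlation), endothelial in 5 of 15 (7 adjusted over the list alone, adjusted p = 0.000849, and adjusted p = 0.391 with an estimated correlation), erythroid in 5 of 9 (6 adjusted over the list alone, adjusted p = 0.00124, and adjusted p = 0.199 with an estimated correlation) and macrophage in 4 of 11 (4 adjusted over the list alone, adjusted p = 0.0264, and adjusted p = 0.471 with an estimated correlation). The Wnt target list rose in 3 of 9 members, and in 3 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.168 with an estimated correlation). The hypoxia and glycolysis list fell in 3 of 13 members and in 5 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.181 with an estimated correlation), with the mitophagy gene Bnip3 down by 2.52. The immediate early and heat shock list fell in 5 of 14 members and 7 adjusted over the list alone (adjusted p = 3e-04, and adjusted p = 0.254 with an estimated correlation). Its member Fos, a transcription factor gene that stress induces within minutes, fell by 4.19 (SE 1.21, adjusted p = 0.0169), which became -3.93 (adjusted p = 0.0505) without renal vesicle replicate 1. The mesenchyme arrays themselves split on this list by the way the titles say tissue was obtained, as the plot of Fos and Egr1 shows. Against the 3 mesenchyme arrays titled LCM alone, 379 genes were called. Against those titled dissection or collagenase alone, the count stayed within 1.5 times of the main 1854. The part that the way of obtaining the tissue has in the calls and list falls of this comparison was not tested.

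**Figure D2:**
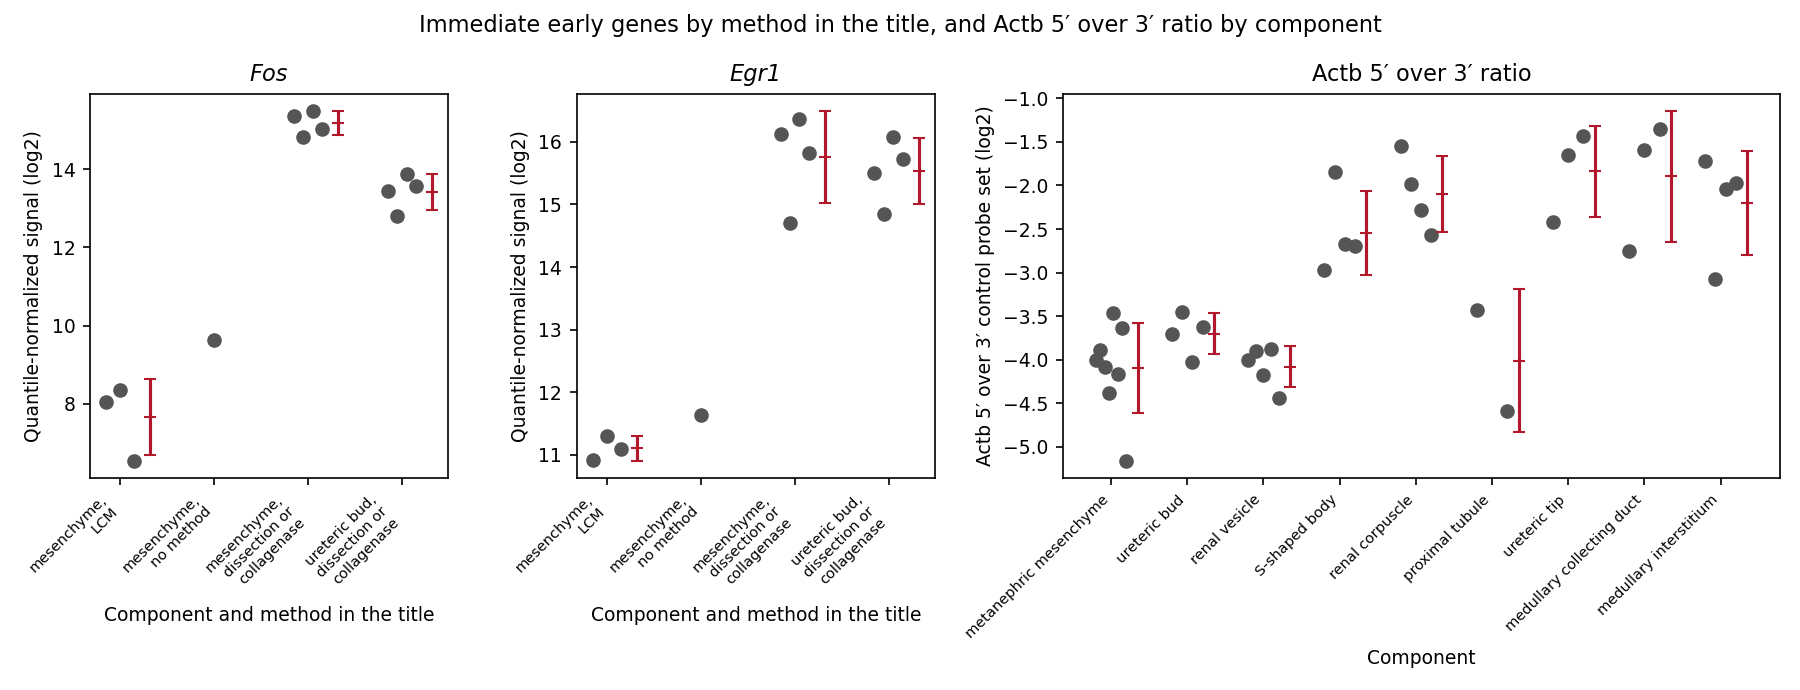
Quantile-normalized log2 signal of Fos and Egr1 in the E11.5 arrays by component and by the method in the title (points, 1 per array; bar, mean with SD), and the log2 ratio of the 5′ to the 3′ Actb control probe set in every array by component. Fos was 7.52 higher in the 4 mesenchyme arrays titled dissection or collagenase than in the 3 titled LCM, and the mean Actb ratio lay between -4.10 and -3.70 in the 3 earlier components, at -4.01 in the proximal tubule and between -2.55 and -1.84 in the other components.

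The S-shaped body was compared with the renal vesicle to follow the nephron as it patterns into segments. The podocyte phosphatase gene Ptpro (probe set 1417676_a_at) reached 13.75 ± 1.61 (SD, n = 4) against 6.87 ± 0.75 (SD, n = 5) and rose by 6.88 (SE 0.79, adjusted p = 3.62e-07). The podocyte genes Synpo and Podxl rose by 4.67 (SE 0.85, adjusted p = 0.000782) and 3.94. Some genes known from later tubule segments rose: the endocytic receptor gene Lrp2 by 4.37 (SE 0.79, adjusted p = 0.000693), the glucose transporter Slc2a2 by 5.53, the scaffold Pdzk1 by 4.02, and the distal homeobox genes Irx2 and Irx1 by 3.67 and 2.64. The Bmp antagonist Sostdc1 rose by 5.76 and Hdc, which makes histamine, by 5.74. The progenitor genes Eya1, Osr1 and Crym fell by 4.23 (SE 0.94, adjusted p = 0.00547), 2.76 and 2.90. The hyaluronan synthase gene Has2 fell by 4.70 and the vesicle signal Bmp2 by 3.01. These genes differed without overlap, which the rule for naming the largest changes required. The Actb control ratio also differed between the 2 components (-2.55 against -4.08), though the Gapdh control ratio did not (-4.96 against -4.95). With the Actb ratio as a covariate, chosen after it was seen, 6 of these genes were not called. Synpo was at 3.96 (SE 1.13), Podxl at 3.31 (SE 0.96), Eya1 at -3.36 (SE 1.24), Osr1 at -2.17 (SE 0.75) and Bmp2 at -1.93 (SE 0.79), with smaller folds and larger errors, while Crym, at -2.88 (SE 0.96), kept its fold and only its error grew. By limma, 517 genes were called higher and 273 lower. The ranges of 1029 genes did not overlap (6.55%, against 1.59% by chance). Nfia and Gopc, called at 5.79 and 5.53 higher, had 4 and 2 other probe sets, none of which was called in that direction. The loop and distal tubule list rose in 5 of 10 members and 7 adjusted over the list alone (median 2.38, adjusted p = 3.65e-07). The podocyte list had 5 rises and 1 fall among 17 members, or 7 and 1 adjusted over the list alone (adjusted p = 1.68e-06, and adjusted p = 0.108 with an estimated correlation). The endothelial list rose in 5 of 15 members and 8 adjusted over the list alone (adjusted p = 3.12e-08, and adjusted p = 0.145 with an estimated correlation). The proximal tubule list rose in 4 of 21 members and 5 adjusted over the list alone (median 1.26, adjusted p = 6.88e-07, and adjusted p = 0.163 with an estimated correlation). The nephron progenitor list fell in 3 of 13 members and 5 adjusted over the list alone (adjusted p = 0.000831, and adjusted p = 0.207 with an estimated correlation). With the library labelled S-shaped body replicate 3 and the library labelled renal corpuscle replicate 4 left out, the podocyte list rose in 4 of 17 members (median 0.51, adjusted p = 9.53e-05), the endothelial list in 2 of 15 (median 1.52, adjusted p = 7.89e-06) and the proximal tubule list in 4 of 21 (median 0.49, adjusted p = 0.0193). Without S-shaped body replicate 3, 336 genes were called, and without renal vesicle replicate 1, 504.

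The renal corpuscle was compared with the S-shaped body, the structure whose proximal end becomes the glomerulus. Most calls were falls. Dnajc22, a chaperone gene (probe set 1460468_s_at), was 6.28 ± 0.58 (SD, n = 4) against 10.51 ± 0.80 (SD, n = 4) and fell by 4.23 (SE 0.65, adjusted p = 0.00121). This call rested on 1 probe set: with probe sets of suffix _x_at or _s_at left out, Dnajc22 was at -1.47 and not called. Slc2a2 fell by 4.56 (SE 0.94, adjusted p = 0.0192), the amino acid transport partner gene Cltrn by 4.00 and Irx2 by 3.23. Calls for the latter 3 were lost without single libraries: Slc2a2 was at -4.49 (adjusted p = 0.055) and Irx2 at -3.26 (adjusted p = 0.0545) without S-shaped body replicate 4, and Cltrn at -3.20 (adjusted p = 0.0702) without renal corpuscle replicate 3. The adenylate kinase gene Ak1 rose by 2.66 (SE 0.48, adjusted p = 0.00822). By limma, 16 genes were called higher and 75 lower. The ranges of 559 genes did not overlap (3.56%), close to the 2.86% given by chance. In marker genes, 2 arrays lay with or nearer to the other component. In the library labelled S-shaped body replicate 3, the slit diaphragm gene Nphs1 was at 12.28, within the 11.09 to 12.59 of renal corpuscle replicates 1 to 3. The Notch ligand gene Dll1 was at 11.66 there and at 12.95 in the library labelled renal corpuscle replicate 4. Both values lay between renal corpuscle replicates 1 to 3 (8.6 to 10.9) and the other S-shaped bodies (13.49 to 14). In the library labelled renal corpuscle replicate 4, Nphs1 was at 7.37, against 7.64 to 7.69 in the other 3 S-shaped bodies, and the vesicle genes Lhx1 and Wnt4 were at 12.69 and 13.54. No member of the podocyte list was called (0 of 17, and 0 adjusted over the list alone, adjusted p = 0.00024, and adjusted p = 0.207 with an estimated correlation). The renal vesicle list fell in 1 of 15 members and in 3 adjusted over the list alone (adjusted p = 3.58e-06, and adjusted p = 0.206 with an estimated correlation), and the loop and distal tubule list in 1 of 10 and 4 (median -1.52, adjusted p = 4.69e-05). With both of these libraries left out, an alternative chosen after their genes were seen, 640 genes were called, 236 higher and 404 lower, among them 60 of the 91. The podocyte list then rose in 6 of 17 members (median 1.63, adjusted p = 1.29e-11), the renal vesicle list fell in 13 of 15 (median -3.30, adjusted p = 7.08e-18) and the loop and distal tubule list fell in 5 of 10 (median -2.05, adjusted p = 0.000386). Single libraries moved the count of 91 as well: it was 21 without S-shaped body replicate 4, 22 without renal corpuscle replicate 3, 26 without S-shaped body replicate 1, 228 without S-shaped body replicate 3, 304 without renal corpuscle replicate 4 and 371 without renal corpuscle replicate 2. With the title date as a fixed term it was 0 by limma (796 at an unadjusted p under 0.05).

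**Figure D3:**
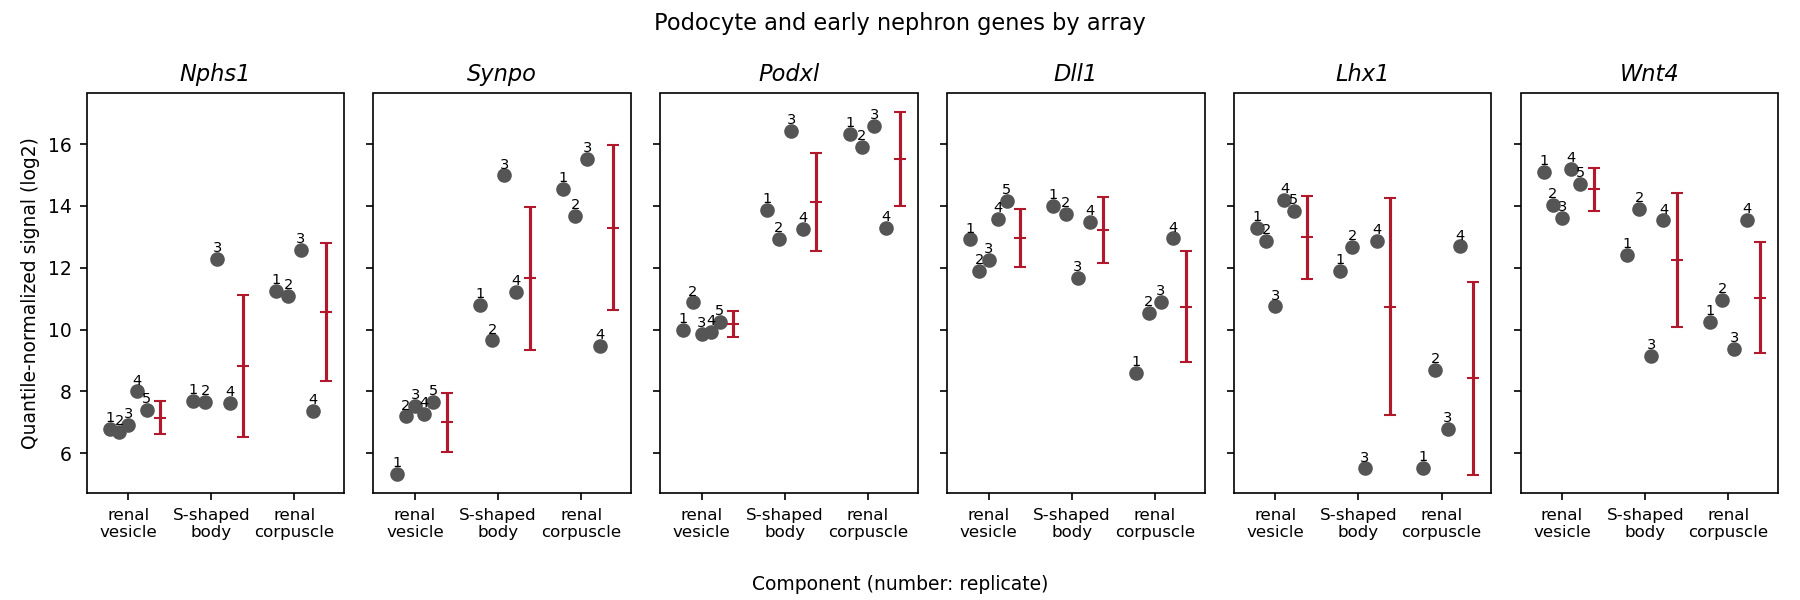
Quantile-normalized log2 signal of 3 podocyte genes (Nphs1, Synpo, Podxl) and 3 early nephron genes (Dll1, Lhx1, Wnt4) in each array of the renal vesicle, S-shaped body and renal corpuscle (points with replicate numbers; bar, mean with SD). Nphs1 was at 12.28 in the library labelled S-shaped body replicate 3 and at 7.37 in the library labelled renal corpuscle replicate 4.

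The proximal tubule was compared with the S-shaped body for the onset of absorptive function. Transport and metabolic genes of the mature tubule were high. Ugt2b37, a glucuronosyltransferase gene (probe set 1449890_at), was 14.44 ± 0.56 (SD, n = 2) against 6.76 ± 1.06 (SD, n = 4) and rose by 7.68 (SE 0.67, adjusted p = 2.85e-09). The thyroid hormone carrier gene Ttr rose by 7.84 (SE 1.11, adjusted p = 8.74e-06), the cation transporter Slc22a2 by 6.62, the cystine transporter subunit Slc3a1 by 6.44, the gluconeogenic enzyme gene Fbp1 by 6.44 and the meprin gene Mep1b by 6.60 (SE 1.49). The Actb control ratio differed here too (-4.01 against -2.55), and with it as a covariate, Mep1b was at 4.84 (SE 1.71, adjusted p = 0.0784), as its fold shrank and its error grew. In the other direction, Ndnf fell by 7.45 (SE 0.85, adjusted p = 4.23e-07) and the regulator Dach1 by 5.87, and the podocyte phospholipase gene Plce1 by 4.42. The Notch genes Hey1 and Jag1 fell by 3.44 (SE 0.72, adjusted p = 0.00148) and 3.33 (SE 0.61, adjusted p = 0.000329), though Jag1 was at -2.35 (adjusted p = 0.0588) without proximal tubule replicate 1. The replication clamp gene Pcna fell by 2.90 (SE 0.34, adjusted p = 5.88e-07). Xist, the noncoding RNA of the inactive X chromosome, fell by 6.47 (SE 2.16, adjusted p = 0.0492), and it ranged between 6.62 and 16.64 over the 37 pools, whose sexes are not given; the call was lost without any of 5 arrays (adjusted p from 0.0635 to 0.309). By limma, 886 genes were called higher and 672 lower, 873 in all without proximal tubule replicate 1, and 74 with the title date as a fixed term. The ranges of 4110 genes did not overlap (26.2%, against 13.3% by chance). The proximal tubule list rose in 18 of 21 members and 20 adjusted over the list alone (median 4.08, adjusted p = 4.8e-19). The Notch pathway list fell in 7 of 10 and 8 (median -2.63, adjusted p = 4.32e-08). The cell cycle list fell in 8 of 24 members and in 14 adjusted over the list alone (median -1.24, adjusted p = 7.1e-10, and adjusted p = 0.2 with an estimated correlation). With 2 proximal tubule arrays, the spread of that group was largely borrowed from the other groups. The 2 arrays correlated at 0.791, and replicate 2 was closer to ureteric tip replicate 3 (r = 0.836).

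The ureteric tip, where branching occurs, was compared with the medullary collecting duct, the differentiating trunk of the same tree. Gsdmc2, a gasdermin gene (probe set 1454883_at), was 6.06 ± 0.98 (SD, n = 3) in the tip against 15.03 ± 0.43 (SD, n = 3) in the duct and fell by 8.97 (SE 0.68, adjusted p = 4.67e-11). The pioneer factor gene Foxa1 fell by 6.34 (SE 0.91, adjusted p = 0.000139), the urothelial plaque gene Upk3a by 5.96 (SE 0.54, adjusted p = 3.67e-09), the peptide hormone gene Apela by 5.84, the actin regulator Pof1b by 4.62 and the ion transport regulator Fxyd4 by 4.04. Higher in the tip, the ubiquitin ligase gene Marchf11 rose by 4.26 (SE 0.66, adjusted p = 0.000395). The catenin gene Ctnnd2 rose by 5.60 (SE 1.09, adjusted p = 0.00905), but its adjusted p was 0.126 without medullary collecting duct replicate 2, 0.0609 without ureteric tip replicate 1 and 0.0676 without ureteric tip replicate 2. Ret was 5.58 higher, at 14.80 ± 0.33 against 9.21 ± 0.84, without overlap, but not called (SE 1.61, adjusted p = 0.19). By limma, 19 genes were called higher and 37 lower, and 917 had an unadjusted p under 0.05. The ranges of 2369 genes did not overlap (15.1%, against 10% by chance). As sets the 2 ends separated clearly. The ureteric tip list was higher in the tip, with 2 of 11 members called and 9 adjusted over the list alone (median 2.64, adjusted p = 1.53e-19). The collecting duct list was lower, with 3 of 11 called and 7 adjusted over the list alone (median -1.91, adjusted p = 1.09e-16). The receptor tyrosine kinase target list was higher, with 1 of 7 called and 3 adjusted over the list alone (median 2.31, adjusted p = 1.02e-09). The cell cycle list was higher in the tip with no member called (0 of 24, and 0 adjusted over the list alone, median 0.98, adjusted p = 1.99e-13, and adjusted p = 0.133 with an estimated correlation). The count of 56 was 14 without medullary collecting duct replicate 2, 28 without its replicate 3, and 21, 13 and 34 without ureteric tip replicates 1, 2 and 3. With the number in the title as a block, Gsdmc2 was still called (1 gene in all), while Foxa1 at -4.82 (SE 0.78), Upk3a at -5.50, Apela at -5.01, Pof1b at -4.53, Fxyd4 at -3.40, Marchf11 at 3.69 and Ctnnd2 at 5.05 were not; this fit used the arrays of the 2 components alone. With the title date as a fixed term, 9 genes were called, and Foxa1 at -6.51 (SE 1.17), Fxyd4 at -4.06 (SE 0.71), Marchf11 at 4.13 (SE 0.86) and Ctnnd2 at 4.83 (SE 1.54) were not. Of these, Foxa1, Fxyd4 and Marchf11 kept their folds and their errors grew. On the 2 dates shared by both components (4 arrays), 638 genes were called, among them all of these and Ret. With 2 means and a date term fitted to 4 arrays, the spread came largely from the variance shared over genes, so these calls carry little weight.

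The ureteric tip at embryonic day E15.5 was compared with the ureteric bud of embryonic day E11.5, the same lineage 4 days earlier, whose titles name dissection or collagenase. Trim71, a repressor of let-7 microRNA activity (probe set 1456673_at), was 6.75 ± 1.07 (SD, n = 3) against 12.21 ± 0.36 (SD, n = 4) and fell by 5.46 (SE 0.87, adjusted p = 0.000141). Sall4, a pluripotency factor gene, fell by 4.66 (SE 0.90, adjusted p = 0.00136), the semaphorin gene Sema5b by 4.91, the matrix link gene Hapln1 by 4.78 and the calcitonin receptor gene Calcr by 4.16. The early response gene Egr2 fell by 5.49 (SE 1.27, adjusted p = 0.00753). The epithelial factor gene Ehf rose by 4.99 (SE 0.93, adjusted p = 0.000997), the transporter Slco4c1 by 5.58 and Fxyd4 by 2.83. The Actb control ratio was -1.84 in the tip and -3.70 in the bud, while the Gapdh control ratio went the other way (-4.77 and -3.08). With the Actb ratio as a covariate, chosen after it was seen, 5 of these genes were not called. Ehf was at 3.76 (SE 1.25), Fxyd4 at 1.62 (SE 0.76) and Sall4 at -3.70 (SE 1.21), with smaller folds and larger errors, while Egr2 at -5.31 (SE 1.76) and Slco4c1 at 5.12 (SE 1.58) lost their calls mainly to a larger error. Stromal and progenitor genes were higher in the tip samples. Col3a1 rose by 4.92 (SE 0.64, adjusted p = 4.46e-06) and Penk, an enkephalin precursor gene of stroma, by 4.43. The progenitor genes Itga8 and Sall1 rose by 4.41 and 4.97, and each of these genes was called. The interstitium list rose in 11 of 19 members and 17 adjusted over the list alone (median 3.16, adjusted p = 4.21e-22). The nephron progenitor list rose in 4 of 13 and 6 (median 1.62, adjusted p = 9.08e-09), but neither list was called in the tip over the collecting duct (adjusted p = 0.793 and 0.949). Over the bud, the ureteric epithelium list had no member called (0 of 14, median -0.03). The immediate early and heat shock list fell in 3 of 14 members and 9 adjusted over the list alone (adjusted p = 0.000404, and adjusted p = 0.262 with an estimated correlation). For 2 further lists, renal vesicle and mesangial and mural, the test was upward (adjusted p = 0.000484 and 0.00869) while the median was -0.04 and -0.05; these became adjusted p = 0.364 and adjusted p = 0.291 with an estimated correlation. The ranges of 5308 genes did not overlap (33.8%, against 5.71% by chance). By limma, 321 genes were called higher and 344 lower, beside a median over all genes of -0.22. With arrays only scaled, the counts were 685 and 214 and that median was 0.16, so the balance of directions was not settled by the data. The count of 665 was 411, 444, 430 and 419 without ureteric bud replicates 1 to 4, 305, 382 and 415 without ureteric tip replicates 1, 2 and 3, and 22 with the title date as a fixed term. The transcription factor gene Nfia was called at 6.65 higher, and 2 of its 4 other probe sets were called in that direction. For Thoc2, an mRNA export gene called at 5.24 higher, neither of its 2 other probe sets was called.

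The medullary interstitium was compared with the other 5 components of its day. Stromal genes set it apart. Cldn11, a claudin gene (probe set 1416003_at), was 13.70 ± 0.85 (SD, n = 4) against 8.88 ± 1.27 (SD, n = 16) and rose by 4.82 (SE 0.51, adjusted p = 4.87e-07). The homeobox gene Alx1 rose by 4.71 (SE 0.56, adjusted p = 1.37e-06), the T-box gene Tbx18, which marks cells around the ureter, by 4.91, the ephrin receptor gene Epha3 by 4.91, the Bmp antagonist gene Vwc2 by 4.83, the cofactor gene Dach2 by 4.54 and the secretion gene Cadps by 4.52. In all 4 arrays these exceeded all 16 others, which the rule for naming the largest changes required. The matrix proteoglycan genes Lum and Ogn rose by 4.14 and 3.70. The macrophage receptor genes Mrc1 and Cx3cr1 rose by 4.04 (SE 0.75, adjusted p = 0.000609) and 3.34. Fras1, a basement membrane adhesion gene of epithelia, fell by 2.41 (SE 0.34, adjusted p = 1.99e-05), the protease gene St14 by 3.02 and the laminin chain gene Lama5 by 3.79. By limma, 548 genes were called higher and 414 lower. The interstitium list rose in 12 of 19 members and 17 adjusted over the list alone (median 1.66, adjusted p = 6.34e-14). The macrophage list rose in 6 of 11 and 8 (median 2.03, adjusted p = 7.52e-09). The epithelial junction and keratin list fell in 7 of 16 members and 14 adjusted over the list alone (adjusted p = 1.56e-10, and adjusted p = 0.112 with an estimated correlation). The count of 962 was 409 without medullary interstitium replicate 3 and 490 without its replicate 4. Some of its title dates are shared with other components. With the date as a random block, 971 genes were called, and with the date as a fixed term 12, among them Vwc2 and Cadps. Alx1 was then at 4.95 (SE 0.91), Cldn11 at 4.32 (SE 0.75), Dach2 at 4.39 (SE 0.82), Epha3 at 5.04 (SE 1.26), Cx3cr1 at 3.08 (SE 0.69) and Fras1 at -1.94 (SE 0.44), and the other genes named were not called either.

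The renal corpuscle was set against the other 5 components of its day. Ptpro was 15.28 ± 1.76 (SD, n = 4) against 10.63 ± 2.56 (SD, n = 16) and rose by 4.65 (SE 0.66, adjusted p = 4.51e-05). Synpo and Podxl rose by 3.71 and 3.28, the hypotensive peptide gene Adm by 3.19, which is made by podocytes and vessels, and the Notch target Hey1 by 2.49. All 5 overlapped with arrays of other components; without the library labelled S-shaped body replicate 3 and the library labelled renal corpuscle replicate 4, Ptpro, Synpo and Podxl did not. Endothelial genes rose too, with the cell adhesion gene Pecam1 up by 2.42 (SE 0.54, adjusted p = 0.00494) and the endothelial receptor gene Notch4 by 1.86, above every other array. The call for Adm was lost without renal corpuscle replicate 3, at 2.36 (adjusted p = 0.0799). By limma, 318 genes were called higher and 534 lower. The podocyte list rose in 12 of 17 members and 14 adjusted over the list alone (median 1.80, adjusted p = 3.66e-15). The endothelial list rose in 7 of 15 and 11 adjusted over the list alone (median 1.72, adjusted p = 2.46e-09, and adjusted p = 0.112 with an estimated correlation). The collecting duct list fell in 8 of 11 and 9 (adjusted p = 4.91e-10), and its member Elf5, a ductal factor gene, fell by 2.63. The list of oxidative phosphorylation and fatty acid oxidation fell in 2 of 16 members and 2 adjusted over the list alone (adjusted p = 0.00285, and adjusted p = 0.145 with an estimated correlation). The count of 852 was 451 without renal corpuscle replicate 3 and 1487 without its replicate 2. It was 841 with the title date as a random block and 3 with the date as a fixed term, where Ptpro was at 5.06 (SE 0.92), Synpo at 5.18 (SE 1.00) and Podxl at 4.08 (SE 0.92), none of them called.

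Against the same background, the proximal tubule had 1438 genes called higher and 955 lower by limma (661 in all with array weights), beside a median over all genes of 0.11. Ugt2b37 rose by 8.28 (SE 0.58, adjusted p = 4.16e-12), the anion transporter gene Slc22a19 by 7.74, the lipoprotein gene Apom by 7.62 and the vitamin B12 receptor gene Cubn by 7.32. The proximal tubule list rose in 20 of 21 members and 20 adjusted over the list alone (median 4.58, adjusted p = 8.02e-23). Pcna fell by 2.52 (SE 0.29, adjusted p = 1.08e-07). With arrays only scaled, 1125 genes were called higher and 1238 lower. The count of 2393 was 1336 without proximal tubule replicate 1 and 322 with the title date as a fixed term. The S-shaped body was marked by Irx2, which rose by 3.07 (SE 0.53, adjusted p = 0.00143), the potassium channel gene Kcnj5 by 2.55 and Hey1 by 2.40. Its 112 higher and 118 lower genes included 7 of 10 Notch pathway members (8 adjusted over the list alone, median 1.71, adjusted p = 8.1e-12) and 3 of 10 loop and distal tubule members (5 adjusted over the list alone, median 1.52, adjusted p = 1.8e-07). The count of 230 was 376 without proximal tubule replicate 2, 71 without S-shaped body replicate 1 and 99 without its replicate 4. It was 0 by limma with the title date as a fixed term (630 at an unadjusted p under 0.05) and 170 with the date as a random block. With the library labelled S-shaped body replicate 3 and the library labelled renal corpuscle replicate 4 left out it was 444, and the renal vesicle list rose in 11 of 15 members and the cell cycle list in 9 of 24, against 6 and 1 with them.

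The ureteric tip at embryonic day E15.5 was marked by Slco4c1, which rose by 6.10 (SE 0.94, adjusted p = 0.000453), Ctnnd2 by 4.99, the calcium regulator gene Rgn by 4.04 and the feedback inhibitor Spry1 by 1.84. Ret rose by 6.58 (SE 1.24, adjusted p = 0.00313), at 6.48 (adjusted p = 0.0538) without ureteric tip replicate 2. There were 117 genes called higher and 135 lower by limma. With arrays only scaled they were 110 and 70. The ureteric tip list rose in 7 of 11 members and 11 adjusted over the list alone (median 2.51, adjusted p = 2.1e-17). The count of 252 was 61, 35 and 74 without ureteric tip replicates 1, 2 and 3, and 3 with the title date as a fixed term. The medullary collecting duct was marked by Gsdmc2, which rose by 8.52 (SE 0.52, adjusted p = 8.14e-14), Foxa1 by 6.96, Elf5 by 6.09, Apela by 5.99, Upk3a by 5.91, the hedgehog ligand gene Shh by 5.47, the keratin gene Krt19 by 5.20 and the sodium channel gene Scnn1g by 5.21. There were 217 genes called higher and 82 lower. The collecting duct list rose in 9 of 11 members and 10 adjusted over the list alone (median 2.94, adjusted p = 3.52e-36), and the epithelial junction and keratin list in 5 of 16 and 12 (median 2.17, adjusted p = 1.17e-17). The count of 299 was 48 without medullary collecting duct replicate 2, 106 without its replicate 3 and 109 with the title date as a fixed term.

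**Figure D4:**
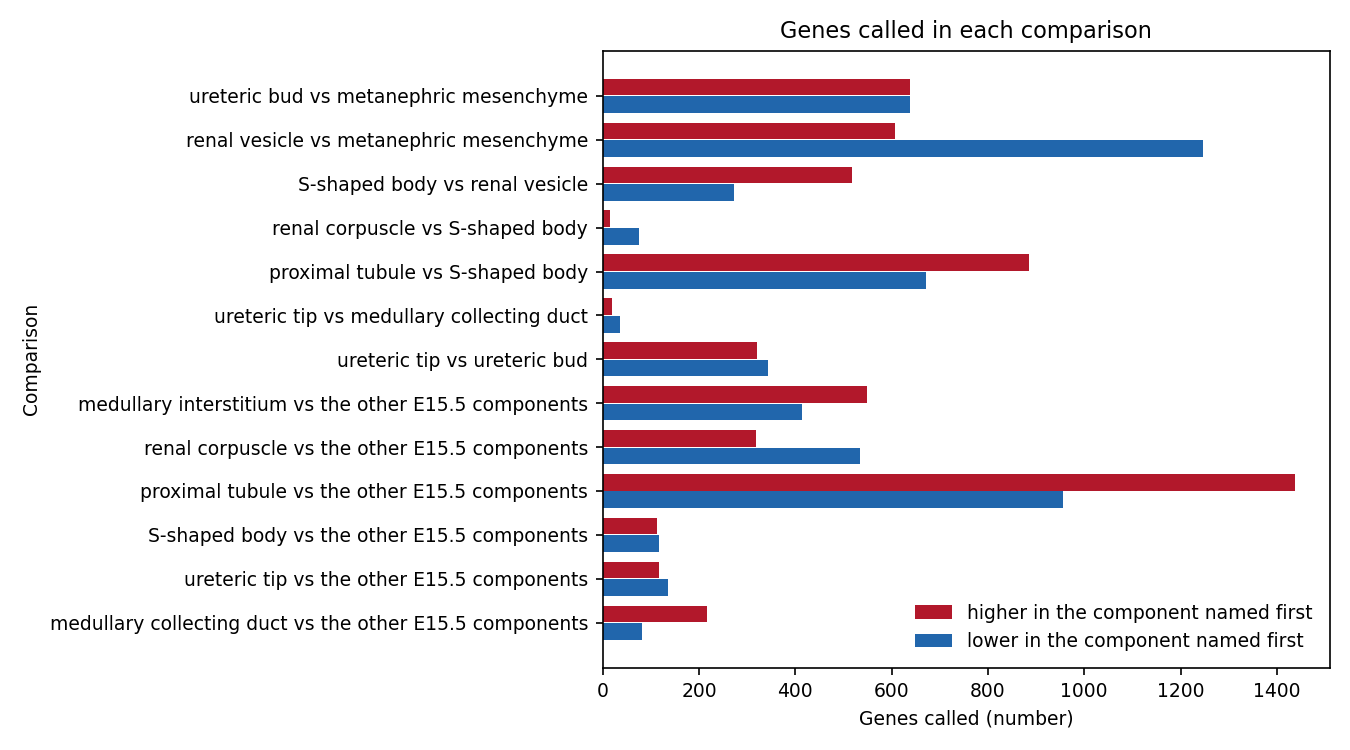
Number of genes called (adjusted p under 0.05 with a log2 fold change of at least 1 in size) in each of the 13 comparisons, higher (red) and lower (blue) in the component named first. There were 19 higher and 37 lower for the ureteric tip over the medullary collecting duct, and 1438 higher and 955 lower for the proximal tubule over the other components.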

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

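The tests of exchanged or mixed libraries, of the way of obtaining the tissue, of embryonic day alone and of other splits were chosen only after the result was seen; those of fragment length through other probe sets and within groups were set before, except the look at genes lower in the tip. In groups of 4 to 10 arrays, 26 measures (list scores, correlations and signal measures) were examined for a single array far from its group, in 156 groups, where chance gives about 1 in 20, or 7.8. There were 12 such arrays and measures. S-shaped body replicate 3 stood apart in 6: its scores were -2.07 for the ureteric tip list (nearest other array -0.777), 3.27 for proximal tubule (0.029), 2.64 for loop and distal tubule (1.64), 1.57 for interstitium (-0.429), 0.123 for the Notch pathway (1.62) and -1.44 for Wnt targets (0.366). Renal corpuscle replicate 2 stood apart at 1.51 for nephron progenitor (-0.731) and 1.20 for interstitium (-0.067). Metanephric mesenchyme replicate 2 was at 0.659 for ureteric tip (0.141), ureteric bud replicate 3 at -0.372 for proximal tubule (-0.654) and renal vesicle replicate 2 at 0.215 for epithelial junction and keratin (-0.872). The mean correlation of metanephric mesenchyme replicate 8 with its group was 0.901 (0.94).

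The libraries labelled renal corpuscle replicate 4 and S-shaped body replicate 3 each resembled the other component. Over 640 genes, with the S-shaped body at 0 and the corpuscle at 1, the median position was 0.178 for the former and 0.775 for the latter, so the smaller of their distances from the end of their own label was 0.775, and exchanged labels may explain it. With each left out of its own scale, renal corpuscle replicates 1, 2 and 3 lay at 0.659, 0.305 and 0.889. S-shaped body replicates 1, 2 and 4 lay at 0.133, 0.195 and 0.0997. Renal corpuscle replicate 2, whose label was not doubted, thus also lay nearer the S-shaped body, so position alone does not decide. A mixture of both tissues is argued against: the podocyte score of the library labelled renal corpuscle replicate 4 lay at -0.138 relative to the other 3 S-shaped bodies, and the vesicle score of the library labelled S-shaped body replicate 3 at -3.15 relative to them. The proximal tubule score of 3.27 in the latter lay above the highest corpuscle, at 1.09, so proximal tubule in that library stays open. Its loop and distal tubule score of 2.64 lay above the other S-shaped bodies (nearest 1.64). That list was lower in the corpuscle than in the S-shaped body without both libraries (median log2 fold change -2.05). An exchange of labels alone does not account for these 2 scores. A structure collected at another stage of maturation also stays open, as untested.

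Immediate early and heat shock genes were higher in mesenchyme arrays titled dissection or collagenase (mean score 1.21, SD 0.459, n = 4) than in those titled LCM (-0.62, SD 0.341, n = 3), and 14 of 14 members were higher. The lowest of the former exceeded the highest of the latter by 0.927, but this restates the pattern on the arrays that showed it, so handling of living tissue as the cause stays open. A difference between bud and mesenchyme cannot split arrays within the mesenchyme, so its test does not bear on this pattern. In mean list score, like-titled arrays of the 2 differed by 0.0577 (SE 0.272), which leaves open differences in single members. Blood, endothelium or macrophages are argued against, because their lists overlapped, by -1.54 at best. But the epithelial score also differed by title (-3.26 against -1.37), so tissue content was not alike and its part stays open. The methods rest on the titles alone, since the sample descriptions name laser capture throughout, and most titles carry no date, so a difference between dates stays open.

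Probe sets such as those called for Nfia and Gopc were high in arrays of day E15.5 other than proximal tubule and low on earlier days, and 70 genes, not all low in proximal tubule, were called higher both in the tip over the bud and in the S-shaped body over the vesicle (10.6 by chance). Embryonic day alone is argued against for these genes as a set, because the median position of the proximal tubule, whose low Nfia and Gopc had been seen before, was 0.118 between the earlier (0) and later (1) groups, but 26 of the 70 lay past the midpoint, and for them it stays open. Shorter amplified fragments, which the low Actb ratio of the earlier components and the proximal tubule may reflect, would make other probe sets follow rises less. The Gapdh control ratio did not follow the Actb ratio: it was -3.08 in the bud against -4.77 in the tip, and -4.95 in the vesicle against -4.96 in the S-shaped body. Which control reflects fragment length was not settled. The median ratio of other probe sets to the called one was 0.329 in the tip over the bud and 0.591 in the bud over mesenchyme, a difference of -0.262 (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give). Genes, not arrays, were permuted, so this p does not measure the spread between arrays. For genes lower in the tip the ratio was 0.177, lower still, so the difference is not particular to rises and fragment length stays open. Within groups, r with the Actb ratio was 0.129 (permutation p = 0.505). The power of this test was not examined, so it does not decide, and regulation by developmental stage stays open.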

How the results depend on the processing

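Leaving out the 2 doubted libraries, adding the Actb ratio and scaling with each gene's probe set kept were chosen only after the result was seen, as were the tests on other splits; the other alternatives were chosen before the data were examined. Counts of calls stayed within 1.5 times under no filter, the stricter filter, probe sets with suffixes left out and scaling only, for all 13 comparisons. Of 148 named results, 147 kept direction and side of the threshold with scaling only; Gopc in the S-shaped body was at 0.81 and not called, because another of its probe sets then had the highest mean, and with each gene's probe set kept 148 of 148 did. Other settings ended more calls of named results: 85 with the title date as a fixed term (24 unchanged), 17 with only the samples compared (128), 12 with the Actb ratio (33), 7 with the title number as a block (2), 5 with an offset of 1 (143), 4 with array weights (141) and 3 with LCM-titled mesenchyme (19). Precision is limited by the number of arrays and by signals near background, where fold changes are understated. For the values below that moved, the cause was not tested. With only the samples compared, some counts rose and others fell, so the smaller number of arrays does not account for all of these moves. The main fit shares 1 estimate of spread over 9 components, whose correlations between arrays differed. Its p-values may therefore be too small for the more variable components and too large for the more uniform ones.

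With array weights, calls were 951 for the medullary collecting duct, 661 for proximal tubule, 200 for renal corpuscle, 412 for S-shaped body and 2088 for ureteric tip, each over the other components, 512 for proximal tubule over S-shaped body, 512 for S-shaped body over vesicle, 2480 for bud over mesenchyme, 1014 for tip over collecting duct and 3670 for tip over bud. With only the samples compared in the fit, they were 120 for collecting duct, 507 for interstitium, 1506 for proximal tubule, 251 for corpuscle, 43 for S-shaped body and 64 for tip over the others, 156 for proximal tubule over S-shaped body, 122 for S-shaped body over vesicle, 2117 for bud over mesenchyme, 37 for tip over collecting duct, 2943 for tip over bud, and 0 by limma for corpuscle over S-shaped body, where 905 had an unadjusted p under 0.05. With the title date as a fixed term, to which undated arrays add nothing, they were 109 for collecting duct, 12 for interstitium, 322 for proximal tubule, 3 for corpuscle and 3 for tip over the others, 74 for proximal tubule over S-shaped body, 9 for tip over collecting duct and 22 for tip over bud. By limma they were 0 for S-shaped body over the others (630 at an unadjusted p under 0.05) and 0 for corpuscle over S-shaped body (796). Bud over mesenchyme rested on a single array of each that shared a date, so no count is given. Tip over bud likewise used a single dated bud array, and the 2 vesicle comparisons could not be estimated. With date as a random block, corpuscle over S-shaped body gave 43.

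With both doubted libraries left out, calls were 640 for corpuscle over S-shaped body, 406 for S-shaped body over vesicle and 444 for S-shaped body over the others; the proximal tubule list, not called before, was then higher in the corpuscle, reversing its direction (adjusted p = 0.00741, 2 of 21 members called). With the Actb ratio as a covariate, S-shaped body over vesicle gave 174 and tip over bud 306; Synpo, at 4.67 (SE 0.85) before, was at 3.96 (SE 1.13) and not called, as its error grew and its fold shrank. The same holds for Podxl, Eya1, Osr1 and Bmp2 in the S-shaped body, Ehf, Fxyd4 and Sall4 in tip over bud and Mep1b in proximal tubule over S-shaped body. Crym (-2.88), Egr2 (-5.31) and Slco4c1 (5.12) lost their calls mainly to a larger error. An offset of 1 gave 194 for collecting duct and 140 for tip over the others and 17 for tip over collecting duct, and an offset at the median gave 108 for the last. The probe set with the largest variance gave 1215 for S-shaped body over vesicle and 1326 for tip over bud. Vesicle over mesenchyme gave 379 with LCM-titled mesenchyme, where Fos was at -0.18 and Six2 at -1.86, neither called. Bud over mesenchyme gave 2292 with the title method as a fixed term. Tip over collecting duct gave 1 with the title number as a block (705 at an unadjusted p under 0.05) and 638 on the 2 shared dates alone (4 arrays). Of 135 list calls, 32 held with an estimated correlation.

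Leaving out 1 replicate at a time, calls ranged from 48 to 387 for collecting duct, 409 to 1166 for interstitium, 1336 to 2653 for proximal tubule, 451 to 1487 for corpuscle, 71 to 376 for S-shaped body and 35 to 365 for tip over the others, 873 to 1746 for proximal tubule over S-shaped body, 21 to 371 for corpuscle over S-shaped body, 1380 to 1985 for vesicle over mesenchyme, 336 to 825 for S-shaped body over vesicle, 960 to 1248 for bud over mesenchyme, 13 to 76 for tip over collecting duct and 305 to 444 for tip over bud. Tip over bud gave 411, 444, 430 and 419 without bud replicates 1 to 4, and 305, 382 and 415 without tip replicates 1, 2 and 3. Leaving out a proximal tubule array leaves 1, which was assumed to vary like the other groups. Among leave-one-out results of named genes, 1839 were on the same side of the threshold, 2 gained a call and 15 lost one, those of Adm, Cltrn, Ctnnd2, Fos, Irx2, Jag1, Ret, Slc2a2 and Xist given with the results.

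Other splits argue against chance for bud and mesenchyme (1 of 100 with as many calls, the real one, 1278 against at most 165), vesicle and mesenchyme (1 of 100, 1854 against 124), S-shaped body and vesicle (1 of 100, 790 against 420) and tip and bud (1 of 35, 665 against 44). Shares were not adjusted. Chance is not excluded for corpuscle and S-shaped body (5 of 35, 91 against 983), where the split with 983 exchanges the 2 doubted libraries. Over the others, splits mix different components and do not decide for interstitium (3 of 100, 962 against 1173), corpuscle (3 of 100, 852 against 1084), S-shaped body (15 of 100, 230 against 1165), tip (12 of 100, 252 against 1398) and collecting duct (8 of 100, 299 against 841). For tip and collecting duct, 10 splits are too few for a share under 0.05 (1 of 10, 56 against 1).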

Other observations

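The tests of these patterns were chosen only after the result was seen, apart from that on other probe sets. In the E15.5 ureteric tip, nephron progenitor and stromal genes were higher than in the bud, beside an unchanged median of the ureteric epithelium list (-0.03). The progenitor genes Sall1 and Itga8 were 4.97 and 4.41 above the bud, among 4 of 13 nephron progenitor members called. Over the medullary collecting duct of the same day, no nephron progenitor or interstitium member was called (median -0.05 and -0.11, camera adjusted p = 0.949 and 0.793). The rise was thus seen against the E11.5 bud, whose titles name dissection or collagenase, so day and tissue handling are confounded with it. Cells of the cap adhering to captured tips alone would raise the nephron progenitor list over the collecting duct as well. Its median there was -0.05 with no member called, which argues against this source for the list as a set. A source shared by tip and duct was not tested. Fragment length was not excluded, since its test gave -0.262 but did not separate rises from falls. With the Actb ratio as a covariate, Sall1 and Itga8 remained called in the tip over the bud.

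Sex-linked transcripts varied between pools: Xist ranged from 6.62 to 16.64, and the Y-linked genes Eif2s3y and Kdm5d from 5.20 to 12.25 and from 5.62 to 11.07. For 8 of the 37 arrays, the closest array belonged to another component. Renal corpuscle replicate 2 was closest to medullary interstitium replicate 2, and the reverse (r = 0.939). Renal vesicle replicate 2 was closest to metanephric mesenchyme replicate 2 (r = 0.931) and medullary collecting duct replicate 1 to ureteric tip replicate 3 (r = 0.928). Medullary interstitium replicate 1 and proximal tubule replicate 2 were also closest to ureteric tip replicate 3 (r = 0.892 and 0.836). The library labelled renal corpuscle replicate 4 was closest to S-shaped body replicate 2 (r = 0.85), and that labelled S-shaped body replicate 3 to renal corpuscle replicate 1 (r = 0.846).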
